A study of Mus musculus with 4 samples.

How the data were processed

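The series holds 4 Agilent two-colour Whole Mouse Genome arrays from 1 slide and 1 scan, so slide and scan cannot differ between groups. RNA came from fluorescent collecting duct and ureteric bud cells sorted at postnatal day 1, per the labels' protocols, with 0.5 µg per labelling reaction. Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1. The deposited files give each spot's intensity in Cy3 and Cy5 as a median over pixels with a local background, a background-subtracted signal, and a processed signal that the software corrected for background and dye bias, per the file headers. The deposited log10 ratio is that of Cy5 over Cy3 processed signal, and the deposited p-value is the software's own for that ratio, per the file headers. Other deposited columns flag spots as well above background, saturated or non-uniform, per the file headers. The deposited series table was identical to this log10 ratio in 45018 of 45018 spots on each array, with medians of 0.182 on KO_vs_WT replicate 1 and 0 on the others, so its scale and direction (Cy5 over Cy3) are known. Whether replicate arrays came from separate animals is not given in the sources used here. P-values therefore measure only the spread between these arrays, which may be technical.

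Groups were taken from the source name of each channel, since titles and descriptions conflict with it. The profile of the Cy3 channel of KO_vs_WT replicate 2, labelled pool 2, correlated at r = 0.996 across genes with Cy3 of the self array whose source is pool 2 and at 0.955 with that of pool 1. The design fixed before the data were examined was limma on log2(Cy5/Cy3), with normexp background correction (offset 50), loess within arrays and control spots at weight 0. The contrast was KO_vs_WT minus WT_self, meant to remove gene-specific dye effects. On KO_vs_WT replicate 1, with almost no Cy3 signal, it cannot do so and can instead carry the dye effect of the self arrays. The gene lists, the naming rule, the size count and the other settings tried were also fixed before the data were examined. The plan named mean signals, but the files give median signals, which were used in their place. Of 45018 spots, 43379 were not controls and covered 41174 probes. Through their accessions 22951 probes matched a symbol in a RefSeq table of GRCm38.p6 (16358 symbols), and other probes kept the file's name or ID. Probes entered if well above background in the channel of 1 genotype on both KO_vs_WT arrays with outlier flags on at most 1 array. Since Cy3 of KO_vs_WT replicate 1 held only 28 such probes, entry rested almost wholly on Cy5, the knockout channel. Genes detected only in wild type could therefore hardly enter. The brightest probe stood for a gene, giving 15913 genes, 10379 with a symbol. No spot was saturated.

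The Cy5 comparison was added after the Cy3 channel of KO_vs_WT replicate 1 was seen to be empty. It used Cy5 of all 4 arrays with normexp (offset 50) and quantile normalization, probes well above background in Cy5 on both arrays of 1 genotype, and the same limma test (15983 genes, 10436 with a symbol). A dark patch of WT_self replicate 1 (479 spots, of which 36.1% of the brighter ones had lost over 2 log2 units) was left out. The log-ratio comparison kept these spots. The Cy5 comparison sets arrays rather than channels of an array against each other, so differences between arrays and labelling reactions enter it. Levels across the 7 usable channels were quantile normalized together only to describe pools. A probe not well above background on both arrays of a group has only a bound there. Its fold is given as at least the ratio to the higher of its own level and the lowest level of any probe well above background on each array.

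Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 26 lists were tested with camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation, with ranks and with fry. In the log-ratio comparison 7 lists passed with ranks and 0 with fry, and in the Cy5 comparison 10 and 0. The naming rule took Atp6ap2, the 12 genes with the largest change in each direction among those that passed, or failing that the smallest unadjusted p with both knockout arrays on the same side of both self arrays, and up to 4 members of each list with the smallest p. Genes without a symbol of their own were counted and not named, and a few genes chosen by the rule are not reported here. Of the 24 such genes in the log-ratio comparison, the text names the first 2 in each direction, a choice made after the empty channel was seen. Of the named genes of the Cy5 comparison, 23 had more than 1 tested probe, and in 4 these differed in sign. Percentiles of list medians come from 10000 random lists matched on level.

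The scripts were tested on simulated data. With gene variances drawn from the spread fitted to these arrays, the log-ratio comparison recovered 29 of 100 genes changed 2-fold and 91 of 100 changed 4-fold among 15913 genes, with 8 unchanged genes called, and the Cy5 comparison recovered 17 and 88 of 100 among 15983, with 5 called. With signals simulated at the scanner level the estimated log2 change was 0.756 to 0.764 of the true one. Both simulations put the full change on both knockout arrays, and the latter gave KO_vs_WT replicate 1 a working Cy3 channel. In the data that channel was almost empty, so the log-ratio values of both simulations do not describe the real log-ratio comparison. Alternatives covered background correction, normalization, dye handling, probe filters, the test, the replicate block and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.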

Results

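Collecting duct and ureteric bud cells of newborn mice with a targeted (pro)renin receptor gene were compared with the same cells of wild-type mice on 4 two-colour whole-genome arrays. The receptor is encoded by Atp6ap2, whose product is also an accessory protein of the vacuolar proton pump. The ureteric bud is the branching epithelium that forms the collecting ducts, and the HoxB7 promoter, active in it, drove both Cre recombinase and green fluorescent protein. Fluorescent cells were sorted at postnatal day 1 from mice with floxed or wild-type receptor alleles, and 0.5 µg of total RNA from pooled cells entered each labelling reaction. On 2 arrays, KO_vs_WT replicates 1 and 2, knockout RNA carried Cy5 and wild-type pool 1 or 2 carried Cy3. On the other two, WT_self replicates 1 and 2, a wild-type pool (1 or 2) carried both dyes. The labels conflict. The titles name the knockout-against-wild-type arrays as wild type and the self arrays as knockout, and the descriptions exchange the pools of the self arrays. The groups here follow the source named for each channel. If the titles were right instead, every direction between knockout and wild type below would turn. The labels do not number the knockout pool of either array, although the series' design names 2 knockout pools.

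Signal differed strongly between channels. In Cy5, 22713 and 20794 of 41174 probes were well above background on KO_vs_WT replicates 1 and 2, and 20025 and 18421 on WT_self replicates 1 and 2. In Cy3 the numbers were 28, 18569, 14935 and 16500 in the same order. The wild-type channel of KO_vs_WT replicate 1 was therefore almost empty, and its spike-in controls, synthetic transcripts added in labelling, had a median background-subtracted signal of 0.266 against 4606 in Cy5 of the same array. Spike-in signal was also low in every channel that carried wild-type pool 2, although these channels measured the cells' own transcripts. It was 57.6 in Cy3 of KO_vs_WT replicate 2, and 5.60 in Cy5 and 50.4 in Cy3 of WT_self replicate 2. The remaining channels with signal read 893 to 4606. No dye swap of knockout against wild type was part of the series as labelled. The number of arrays, 2 per group, limits the precision of all values.

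**Figure D1:**
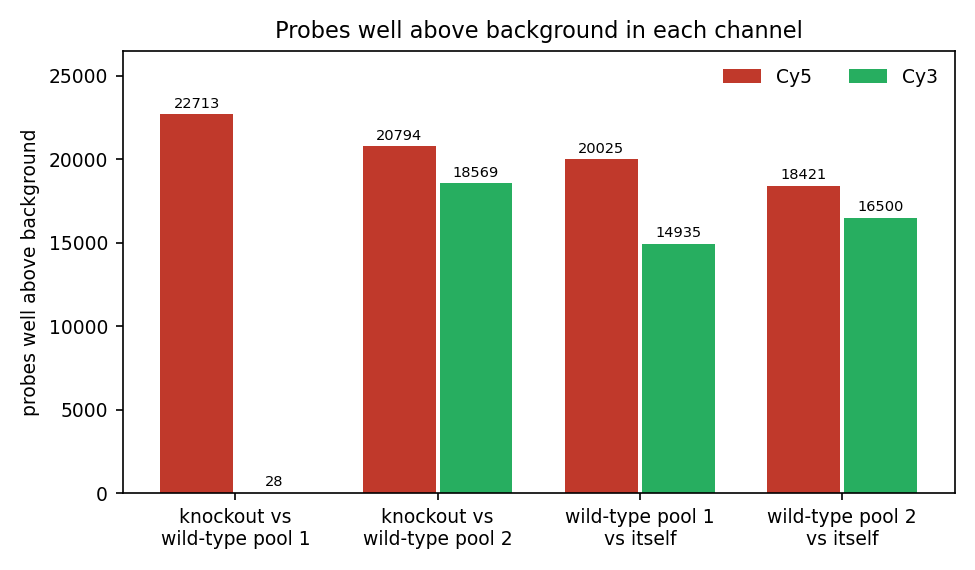
Number of probes well above background (y axis) in the Cy5 and Cy3 channel of each of the 4 arrays (x axis, named by the RNA hybridised). The Cy3 channel of the first array holds 28 such probes, against 14935 to 22713 in the other channels.

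Atp6ap2, the targeted gene, was measured first on every array. Its Cy5 level was 8.08 and 7.72 on the log2 scale on KO_vs_WT replicates 1 and 2 and 8.38 and 8.51 on WT_self replicates 1 and 2, so that both knockout values lay below both wild-type values. The difference was -0.55 ± 0.17 (SE, n = 2 arrays per group, limma adjusted p = 0.806), or 0.716 of the level in wild-type pool 1 and 0.654 of that in pool 2. As a log2 ratio of Cy5 over Cy3, Atp6ap2 stood at 0.024 and -0.63 on KO_vs_WT replicates 1 and 2 and at 0.12 and 0.25 on the self arrays, a difference of -0.49 ± 0.24 (SE; limma adjusted p = 0.914). The ratio on KO_vs_WT replicate 1 has no wild-type signal below it. Without that array the difference was -0.81 (limma adjusted p = 2.6e-07), without KO_vs_WT replicate 2 it was -0.16, and the Cy5 difference without WT_self replicate 1 was -0.61 (adjusted p = 0.0377). Each of these p-values rests on 1 array in a group and on the spread of the other group alone. With the processed signals of the scanner software Atp6ap2 stood at 0.29 where the median of all genes was 0.88, so it still lay below the typical gene. Where the probe lies relative to the deleted part of the gene is not known here, so the value checks the labels only as far as RNA level follows the deletion.

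The planned comparison asked which genes differ between knockout and wild-type cells, as log ratios on the knockout-against-wild-type arrays minus those on the self arrays. Genes of the proximal tubule, the nephron segment that recovers filtered solutes, were lower in knockout, with a median log2 difference of -1.62 over 13 measured genes (camera adjusted p = 2.3e-05). Genes of the loop of Henle and distal tubule had a median of -0.85 over 9 genes (adjusted p = 0.00102), the renin-angiotensin genes -0.43 over 8 (adjusted p = 0.0186) and cholesterol synthesis genes -0.18 over 18 (adjusted p = 0.00558). Genes of glycolysis and hypoxia were higher, with a median of 0.22 over 20 genes (adjusted p = 0.00102), as were principal cell markers at 0.20 over 16 (adjusted p = 0.0246) and immediate early and heat shock genes at 0.14 over 19 (adjusted p = 0.0461). These 7 of 26 lists passed camera with its preset correlation, none did with an estimated correlation (adjusted p = 0.719 for each of the 7), and 0 of their members passed over all genes or adjusted over the list alone. Without KO_vs_WT replicate 2, the only knockout-against-wild-type array with signal in Cy3, 0 lists passed and the medians of the proximal tubule, glycolysis, immediate early and principal cell lists changed sign, to 0.040, -0.049, -0.045 and -0.020, while the loop, renin-angiotensin and cholesterol medians were -0.093, -0.15 and -0.069. Without KO_vs_WT replicate 1 these 3 medians were -1.61, -0.70 and -0.34. KO_vs_WT replicate 2 set knockout against wild-type pool 2, so the list differences above rest mainly on that pool. In Cy5 against pool 1 the cholesterol median had the opposite sign, at 0.20. The renin-angiotensin, loop and proximal tubule medians were -0.067, -0.13 and -0.46 there. Those of the glycolysis, immediate early and principal cell lists were 0.32, 0.36 and 0.33. Without WT_self replicate 2 the principal cell list (adjusted p = 0.0552) and the immediate early list (adjusted p = 0.107) no longer passed. Under median centring the median of all genes moved to 0.44, and the cholesterol list, at 0.50 there, no longer lay below it (adjusted p = 0.314).

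No single gene passed in that comparison. Of 15913 genes, 0 were higher and 0 lower at an adjusted p under 0.05 in limma, with 86 at an unadjusted p under 0.05 (10 higher, 76 lower) where 796 would be expected by chance. The smallest adjusted p was 0.914. Genes detected only in wild type could hardly enter this comparison, so the count of 0 lower does not cover them. The first 2 genes higher by the naming rule were Mcm6, a subunit of the replicative DNA helicase, at 0.49 ± 0.16 (SE), and Ppp1r14b, an inhibitor subunit of protein phosphatase 1, at 0.32 ± 0.11. The first 2 lower were Ddx58, which encodes the RNA sensor RIG-I, at -0.53 ± 0.13, and Igbp1, a regulatory partner of protein phosphatase 2A, at -0.54 ± 0.16, each at an adjusted p of 0.914. Ppp1r14b read -0.011 and 0.0048 on KO_vs_WT replicates 1 and 2, so its difference came from the self arrays, at -0.35 and -0.30. Ddx58 had no probe in the Cy5 comparison, which left out the dark patch of WT_self replicate 1 that the log-ratio comparison kept. Its ratio was 0.39 on WT_self replicate 1 and 0.18 on WT_self replicate 2. The SD of the log2 ratios over genes was 0.123 and 0.476 on KO_vs_WT replicates 1 and 2 and 0.158 and 0.0800 on the self arrays, and the ratios of the KO_vs_WT arrays correlated at r = 0.0505 across genes, which are not independent replicates. By size, 0 genes differed at least 2-fold the same way on both KO_vs_WT arrays and on no self array, and 0 did so with the groups exchanged. Both counts could hardly be other than 0, since only 3 genes were past 2-fold on KO_vs_WT replicate 1 and 0 on WT_self replicate 2. Leaving out KO_vs_WT replicate 1 gave 2997 genes higher and 2218 lower, and 552 by size, in a fit that takes its spread from the self arrays alone and assumes that the lone knockout array varies like them. Leaving out KO_vs_WT replicate 2 gave 0 higher, 4 lower and 3 by size.

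A comparison of the Cy5 channels, chosen after the empty channel was seen, set knockout RNA on both KO_vs_WT arrays against the wild-type pools in Cy5 on the self arrays. The genes higher in knockout with the smallest unadjusted p, as the naming rule picks them, included Sgk1, the aldosterone-induced kinase that raises sodium channel activity, 2.21-fold over wild-type pool 1 and 2.82-fold over pool 2 (log2 difference 1.32 ± 0.18, SE), and Slc16a3, a lactate exporter (1.43 ± 0.23). Also in this group were Sprr2f (2.18 ± 0.40) and Sprr2e (0.77 ± 0.13), small proline-rich proteins of epithelial envelopes, the protease inhibitor gene Spink8 (2.25-fold over pool 1 and 3.56-fold over pool 2), Pcbd2, a pterin dehydratase (1.11 ± 0.18), and Rph3al, a regulator of exocytosis (1.11 ± 0.20). The inducible heat shock protein gene Hspa1a (0.83, and down to 0.31 by its other probes), the circadian clock gene Per1 (0.76), the intracellular fibroblast growth factor homologue gene Fgf12 (0.74, and 0.097 by its other probe) and the GABA receptor subunit gene Gabrp (0.73) completed it, together with Spata17, not well above background in either wild-type pool and at least 1.65-fold higher in knockout. Those lower in knockout, picked in the same way, included Upk3a, a uroplakin of the urothelial membrane (-1.46 ± 0.28), the glutathione transferase gene Gstm3 (-1.24 ± 0.31), Rgs5, a regulator of G-protein signalling found in pericytes (-0.87 ± 0.19), Lmnb1, which encodes lamin B1 (-0.56 ± 0.12), and the phospholipase A2 receptor gene Pla2r1 (-0.62 ± 0.15). Myh7, a cardiac and slow muscle myosin heavy chain, stood at -0.75, the acyl-protein thioesterase gene Lypla1 at -0.53 (-0.16 by another of its probes), the dipeptidase gene Cndp2 at -0.51, the gastrin-releasing peptide gene Grp at -0.50, Fam107a at -0.47 and the histone H4 gene H4f16 at -0.43, and the serine protease gene Tmprss13, not well above background on either knockout array, was at least 1.38-fold lower in knockout.

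None of these genes passed the test. Of 15983 genes in the Cy5 comparison, 0 were higher and 0 lower at an adjusted p under 0.05 in limma, the smallest adjusted p being 0.806 and the smallest unadjusted p 8.01e-04, and 661 had an unadjusted p under 0.05 (479 higher, 182 lower) against 799 expected by chance. By size, 11 genes were over 2-fold higher on both knockout arrays than on both wild-type arrays and 0 lower, while the other splits of the 4 arrays into pairs gave 0 and 0. Those other splits set the knockout arrays against each other, and only 14 and 3 genes were over 2-fold apart between them, so that 0 was nearly fixed beforehand. These 11, named after their values were seen, were Sgk1, Sprr2f, Itga1, Lifr, Myo1e, Pdpk1, Pip4p2, Tgm5, Usp29 and 2 probes without a symbol. A looser rule, at least 2-fold higher in the knockout mean with arrays not overlapping, gave 51 probes. For 9 of their genes that had another probe outside the 51, the other probes showed a median of 4.14% of the difference. Levels did not overlap between genotypes in 39.6% of genes, where chance gives 33.3% and the other splits gave 33.5% and 26.0%. Without WT_self replicate 1 the comparison gave 2534 genes higher, 1695 lower, and 212 and 333 by size. Without KO_vs_WT replicate 1 it gave 46 and 20 by size, and without KO_vs_WT replicate 2 it gave 11 and 1.

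Collecting duct principal cell markers, which serve water and sodium uptake, were higher in knockout. Of 16 measured markers 13 had a positive difference, 11 stood higher on both knockout arrays than in both wild-type pools, and the median was 0.32 (camera adjusted p = 1.33e-04; adjusted p = 0.844 with an estimated correlation). Besides Sgk1 they included the vasopressin-regulated water channel gene Aqp2 (0.74 ± 0.19, SE), the Na,K-ATPase modulator gene Fxyd4 (0.63 ± 0.19) and Scnn1b, a subunit of the epithelial sodium channel (0.56 ± 0.17). The 3 with a negative difference, named after their values were seen, were the potassium channel gene Kcnj1 at -1.14, which is also active in the loop of Henle, the vasopressin receptor gene Avpr2 at -0.22 and the water channel gene Aqp4 at -0.12. Kcnj1 was lower mainly than pool 2, at -2.095, with -0.188 against pool 1. The median of the list was 0.33 against wild-type pool 1 and 0.32 against pool 2, and 0.44 on KO_vs_WT replicate 2 alone, where knockout and pool 2 shared an array. The list also differed between the knockout arrays, with replicate 2 above replicate 1 by a median of 0.098 and in 13 of 16 members. Sgk1 was the 1 member that passed when adjusted over the list alone. Lists of other cell types moved opposite to this group in the comparison with pool 1, with medians of -0.46 for proximal tubule, -0.33 for stroma, -0.36 for endothelium, -0.34 for erythroid and -0.16 for leukocyte genes.

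Genes of glycolysis and hypoxia were higher in knockout in all 20 measured members, with a median of 0.37 (camera adjusted p = 6.66e-10; adjusted p = 0.844 with an estimated correlation), and 16 stood higher on both knockout arrays than in both wild-type pools. Among them were the glucose transporter gene Slc2a1 (0.88 ± 0.16, SE), the glycolytic regulator gene Pfkfb3 (0.86 ± 0.20, and 0.31 by its other probe), the aldolase gene Aldoa (0.69 ± 0.14) and the lactate dehydrogenase gene Ldha (0.63 ± 0.18). Immediate early and heat shock genes, which respond fast to stimulation and handling, were higher in all 19 measured members, with a median of 0.31 (adjusted p = 1.81e-07; adjusted p = 0.844 with an estimated correlation). Besides Hspa1a they included the transcription factor genes Klf6 (0.68 ± 0.16), Jund (0.52 ± 0.15) and Egr1 (0.45 ± 0.12). No member of either list passed, over all genes or adjusted over the list alone. Against pool 1 and pool 2 the medians were 0.32 and 0.44 for glycolysis and hypoxia, and 0.36 and 0.34 for immediate early genes. They also differed between the knockout arrays, with replicate 2 above replicate 1 by 0.24 and 0.15, and the same array stood lower than replicate 1 in endothelial (-0.21), stromal (-0.17) and proximal tubule genes (-0.23). All 3 of these higher lists passed without any 1 of the 4 arrays.

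**Figure D2:**
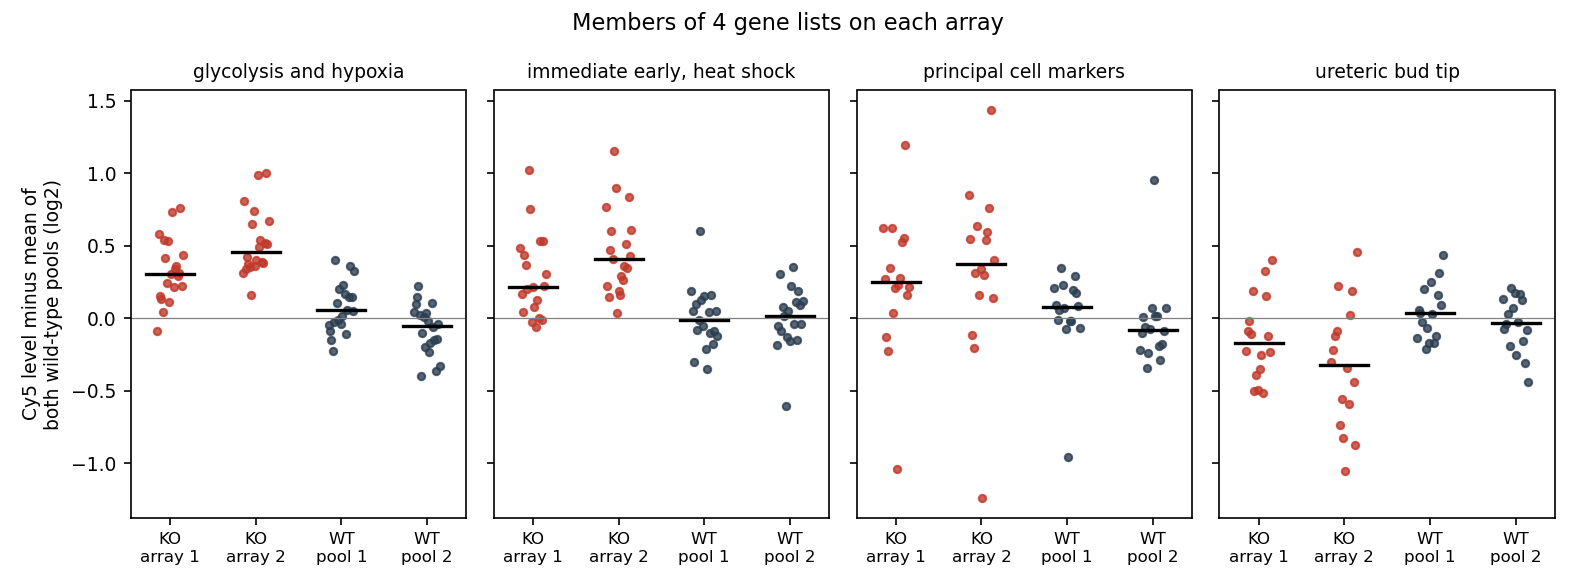
Cy5 level of each measured member of 4 gene lists, minus the mean of both wild-type pools (y axis, log2), on the knockout arrays and in the wild-type pools (x axis). Each point is a gene and the black line is the median, which lies above 0 on both knockout arrays for the first 3 lists and below 0 for ureteric bud tip genes (median knockout minus wild-type difference -0.27).

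Ureteric bud tip genes, active where the duct epithelium branches, were lower in knockout. Of 16 measured members 12 had a negative difference, 10 stood lower on both knockout arrays than in both wild-type pools, and the median was -0.27 (camera adjusted p = 3.63e-04; adjusted p = 0.844 with an estimated correlation). They included Gfra1, a co-receptor for the branching signal GDNF (-0.66 ± 0.19, SE, and -0.35 by its other probe), the transcription factor genes Etv4 (-0.62 ± 0.19) and Etv5 (-0.47 ± 0.13), which act downstream of that signal, and the organic anion transporter gene Slco4c1 (-0.55 ± 0.16), while none passed over all genes or adjusted over the list alone. The median was -0.27 against pool 1 and -0.20 against pool 2. Stromal, endothelial and proximal tubule genes were also lower than in pool 1, with medians of -0.33, -0.36 and -0.46. The list no longer passed without WT_self replicate 1 (median -0.20, adjusted p = 0.105) or with 75th percentile scaling (adjusted p = 0.0832), and its median was -0.17 without KO_vs_WT replicate 2.

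Genes of other nephron segments were lower in knockout, mainly because wild-type pool 2 held far more of them than pool 1 or either knockout array. All 12 measured proximal tubule genes had a negative difference, with a median of -1.80 (camera adjusted p = 1.16e-07; adjusted p = 0.844 with an estimated correlation). The androgen-regulated kidney gene Kap stood at -1.33 against pool 1 and -3.58 against pool 2, the phosphate transporter gene Slc34a1 at -1.03 and -4.21, and Spp2 at -0.82 and -4.12. Over the list the medians were -0.46 and -3.14, which are also the values without WT_self replicate 2 and without WT_self replicate 1. Loop of Henle and distal tubule genes had a median of -0.93 over 8 (adjusted p = 0.00230; adjusted p = 0.844 with an estimated correlation), -0.13 against pool 1 and -1.84 against pool 2. They included the uromodulin gene Umod (-1.41), the salt transporter genes Slc12a1 (-1.28) and Slc12a3 (-0.48), and Ppp1r1a (-1.21, and -0.45 by its other probe). Renin-angiotensin genes had a median of -0.49 over 8 (adjusted p = 0.00221; adjusted p = 0.844 with an estimated correlation), -0.067 against pool 1 and -0.76 against pool 2, with the angiotensin peptidase gene Enpep at -0.80, the angiotensin receptor gene Agtr1a at -0.55 and Atp6ap2 itself. Without WT_self replicate 2 neither the loop list (adjusted p = 0.125) nor the renin-angiotensin list (adjusted p = 0.326) passed. No member of these 3 lists passed over all genes or adjusted over the list alone.

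Endothelial, leukocyte and proliferation genes were lower by smaller amounts, each at a camera adjusted p of 0.0306, with estimated-correlation adjusted p = 0.844, 0.844 and 0.874. The endothelial list had a median of -0.20 over 9 genes, -0.36 against pool 1 and -0.069 against pool 2, among them the tight junction gene Cldn5 (-0.48), the angiogenic secreted factor gene Egfl7 (-0.32), Kdr, a receptor of vascular endothelial growth factor (-0.25), and Plvap (-0.20). The leukocyte list had a median of -0.16 over 13, -0.16 against pool 1 and -0.094 against pool 2, with S100a8 at -0.34, the Fc receptor chain gene Fcer1g at -0.25, and the complement genes C1qa and C1qc at -0.21 each. Of 30 proliferation genes 23 had a negative difference, with a median of -0.042, as in Tyms and Rrm2, both of deoxynucleotide synthesis (-0.26 and -0.28), the cyclin gene Ccna2 (-0.26) and the spindle gene Nusap1 (-0.22). Against pool 1 29 of the 30 were lower, with a median of -0.19, and against pool 2 the median was 0.017. No member of these lists passed over all genes or adjusted over the list alone. None of the 3 lists passed without KO_vs_WT replicate 2 (adjusted p = 0.461, 0.382 and 0.538) or without WT_self replicate 1 (adjusted p = 0.531, 0.291 and 0.867). Without KO_vs_WT replicate 2 the endothelial and leukocyte medians were -0.10 and -0.047. Without WT_self replicate 1 they were -0.069 and -0.094, and without WT_self replicate 2 the endothelial median was -0.36. The proliferation median changed sign without WT_self replicate 1, to 0.017, and its test direction with 75th percentile scaling.

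The other 16 lists did not pass, and no member of them passed over all genes or adjusted over the list alone. The vacuolar proton pump, to which Atp6ap2 belongs, had a median of -0.049 over 23 genes (camera adjusted p = 0.329), with Atp6v1g1 at -0.42, Atp6v1b1 at -0.63 and Atp6v0c at 0.17. Atp6v1g1 and Atp6v1b1 were lower mainly than pool 2, at -0.78 and -1.22, with -0.055 and -0.036 against pool 1. Intercalated cell markers, of the acid-base cells rich in this pump, had a median of 0.064 over 20 (adjusted p = 0.322), with the ammonia transporter gene Rhcg at 0.88, Aqp6 at 0.64 and the transcription factor gene Dmrt2 at 0.45. Against pool 1 and pool 2 the list medians were -0.034 and 0.23, and Aqp6 stood at 0.25 and 1.04. General ureteric bud and collecting duct epithelial genes had a median of 0.12 over 21 and a mean of -0.0076 (adjusted p = 0.329, direction up), with Cdh16 at 0.58, Wnt7b at 0.44 and the uroplakin gene Upk1b at -0.94. The median of this list was 0.044 against pool 1 and 0.27 against pool 2. Wnt target genes had a median of 0.011 over 11 (adjusted p = 0.944), with the transcription factor genes Sp5 at 0.71, Lef1 at -0.22 and Sox9 at 0.17, and the receptor-degrading ligase gene Rnf43 at 0.52. Wnt ligands and receptors had a median of -0.053 over 21 (adjusted p = 0.541), with Wnt4 at 0.43, Wnt11 at -0.55 and Fzd1 at -0.48. Cilium and cystic disease genes stood at 0.057 over 18 (adjusted p = 0.533), with Bicc1 at 0.39, Nek8 at 0.28 and Bbs4 at 0.21. Their median was -0.020 against pool 1 and 0.14 against pool 2, and Bicc1 stood at 0.14 and 0.64.

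Among stress and pathway lists, p53 and apoptosis genes had a median of 0.032 over 19 (camera adjusted p = 0.533), with Pmaip1 at 0.60, Gadd45b at 0.45, Gadd45a at 0.25 and Perp at -0.41. Endoplasmic reticulum stress genes had a median of -0.044 over 22 against a mean of 0.039 (adjusted p = 0.944, direction down), with Ddit4 at 0.72, Atf3 at 0.62, Ddit3 at 0.40 and Dnajb9 at 0.35. Lysosome and autophagy genes had a median of -0.032 over 31 (adjusted p = 0.944), 0.096 against pool 1 and -0.11 against pool 2, with the autophagy receptor gene Sqstm1 at 0.56, Grn at 0.40 (0.11 by its other probe), Gabarapl1 at 0.34 (0.14 by its other probe) and Ctsz at -0.47. Cholesterol synthesis genes had a median of -0.030 over 18 (adjusted p = 0.887), 0.20 against pool 1 and -0.17 against pool 2, with Msmo1 at 0.30, Fdft1 at 0.22 and Mvd at -0.34. TGF-beta and matrix genes had a median of -0.055 over 20 against a mean of 0.016 (adjusted p = 0.944, direction down), with Tgfb3 at 0.47, Ccn2 at 0.42, Tgfbr1 at 0.39 and Col4a2 at -0.25 (-0.12 by its other probe). Inflammation and injury genes had a median of 0.0037 over 14 against a mean of -0.031 (adjusted p = 0.944, direction up), with Socs3 at 0.52, Cxcl16 at 0.51, Clu at 0.40 and Krt20 at -1.45. For Sox9, Dnajb9, Tgfbr1 and Bbs4 the probes of the gene differed in sign.

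Among lists of other cell types, nephron progenitor genes had a median of -0.15 over 6 (camera adjusted p = 0.0888), -0.26 against pool 1 and -0.058 against pool 2, with Crym at -0.33, Cited1 at -0.28, Dapl1 at -0.26 and Osr1 at 0.063, the last turning to -0.20 with 75th percentile scaling. Podocyte and differentiating nephron genes had a median of -0.036 over 8 (adjusted p = 0.824), with Wt1 at -0.29, which was 0.011 without WT_self replicate 1, and Fgf8 at 0.19. Stromal genes had a median of 0.057 over 14, a mean of -0.018 and a test direction of down (adjusted p = 0.582), with Aldh1a2 at -0.56 and Pdgfrb at -0.26. Meis1 stood at 0.24 and at -0.0027 with 75th percentile scaling. Erythroid genes had a median of 0.11 over 4 (adjusted p = 0.944), with Bpgm at 0.13 (0.0029 by its other probe), Hba-a1 at 0.34 and Alas2 at 0.083, of which Hba-a1 and Alas2 were -0.41 and -0.38 without WT_self replicate 2. Stromal and erythroid medians were -0.33 and -0.34 against pool 1 and 0.39 and 0.37 against pool 2.

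**Figure D3:**
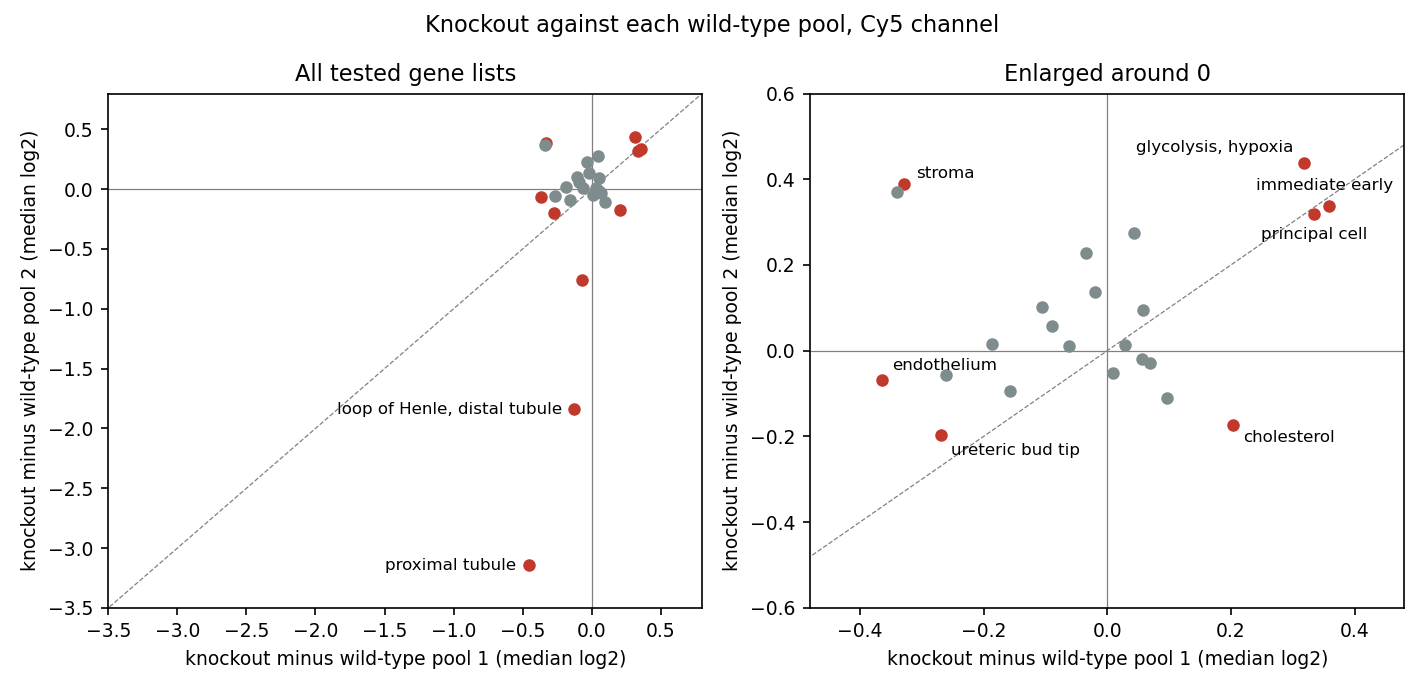
Median log2 difference of each of 26 gene lists, knockout minus wild-type pool 1 (x axis) and knockout minus wild-type pool 2 (y axis). The full range is on the left and an enlarged view on the right. Equal values lie on the dashed line, and red marks a selection of the lists, not all that passed. Proximal tubule genes lie at -0.46 and -3.14, while glycolysis, immediate early and principal cell lists lie at 0.32 to 0.44 on both axes.

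The wild-type pools differed from each other more than the knockout differed from pool 1. Over 15983 genes the SD of the log2 Cy5 difference was 0.471 between the wild-type pools, 0.207 between the knockout mean and pool 1, 0.484 between the knockout mean and pool 2, and 0.154 between the knockout arrays. Between pools 2 and 1, 377 genes were over 2-fold higher and 240 over 2-fold lower. When all 7 usable channels were put on a common scale, the knockout arrays differed by an SD of 0.129, against 0.128 for pool 2 hybridised in Cy3 on separate arrays. The knockout arrays thus differed by about as much as repeat hybridisations of 1 pool. By the same measure Cy5 of KO_vs_WT replicate 1 and of pool 1 differed by 0.158, less than the 0.172 between the dyes of pool 1. This SD therefore cannot show whether channels hold the same pool. With the mean of the knockout arrays taken as 1 sample, the spread comes from the 2 wild-type pools alone. In that fit 0 genes passed in either direction in limma (98 at an unadjusted p under 0.05), and camera called 3 lists higher and 7 lower, which with 1 knockout sample does not separate genotype from pool. Stromal and intercalated cell lists were lower in pool 2 than in pool 1, by medians of -0.71 and -0.34, and proximal tubule and loop lists were higher by 2.69 and 1.81.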

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

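All alternatives of the Cy5 comparison were chosen after seeing the data, and those of the log-ratio comparison were planned. Signal over background limits the log-ratio comparison, since KO_vs_WT replicate 1 has almost no wild-type signal. With probes required to be well above background in both channels on all 4 arrays, 12 genes were left and the gene list tests gave no value. No probe was saturated, so leaving out saturated probes moved nothing. The median of all genes in the log-ratio comparison moved to 0.16 with background-subtracted signals, 0.44 with median centring, 0.88 with processed signals, 0.88 with series table values and -0.40 over those 12 genes. Unless the construction of a setting shows it, the cause of a change was not tested.

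In the log-ratio comparison the gene counts of 0 and 0 became 21 higher and 45 lower with a trended and robust fit. Atp6ap2 passed there at -0.49 (limma adjusted p = 0.0452). The counts became 1096 and 12 by the scanner software's p-value under 0.01 on both KO_vs_WT arrays. Genes that passed the same way on both self arrays were left out. On KO_vs_WT replicate 1 that p-value sets Cy5 against an almost empty Cy3 channel, so 1096 against 12 cannot be read as a genotype difference. The count by size of 0 became 251 with background-subtracted signals, 1 with an offset of 16, 449 with median centring and 1117 with processed signals or series table values. These size counts also use the ratio on KO_vs_WT replicate 1, with the same limit. The 3 higher lists became 1 with scale normalization, and 0 with an estimated correlation or fry, where the 4 lower lists also became 0. Atp6ap2 read 0.29 with processed signals and 0.29 with series table values, and Ddx58 0.41 and Igbp1 0.25 with median centring, all still below the medians of all genes of 0.88, 0.88 and 0.44 in these settings. Ppp1r14b turned to -0.0031 against 0. With 1 array left out the values ranged from 0 to 2997 genes higher, 0 to 2218 lower, 0 to 552 by size, 0 to 3 lists higher, 0 to 6 lower, and -0.81 to -0.16 for Atp6ap2. List medians ranged from -0.020 to 0.47 for principal cells, -0.049 to 0.38 for glycolysis and hypoxia, -0.045 to 0.34 for immediate early genes and -3.24 to 0.040 for proximal tubule.

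In the Cy5 comparison the 3 higher lists became 7 with 75th percentile scaling and 0 with an estimated correlation or fry, and the 7 lower lists became 4 with the stricter filter and 0 with an estimated correlation or fry. The 11 genes over 2-fold higher became 161 with background-subtracted signals, 19 with an offset of 16, 18 with 75th percentile scaling and 7 with wild-type pools averaged over dyes, and the 0 lower became 66 with background-subtracted signals. With 75th percentile scaling the proliferation median was -0.00082 with its test direction turned, Osr1 turned to -0.20, Meis1 to -0.0027 and Aqp4 to 0.019. With 1 array left out the values ranged from 0 to 2534 genes higher, 0 to 1695 lower, 11 to 212 over 2-fold higher, 0 to 333 over 2-fold lower, 3 to 5 lists higher, 4 to 8 lower, -0.73 to -0.37 for Atp6ap2, -0.19 to 0.017 for proliferation, -0.38 to 0.55 for Alas2, -0.60 to 0.011 for Wt1 and -0.41 to 1.10 for Hba-a1. The fit without WT_self replicate 1 takes its spread from the knockout arrays alone.

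Deviations of same-numbered arrays from their group means correlated at -0.082 in log ratios and 0.037 in Cy5 levels across genes, so the numbers are not shown to pair. With the replicate block the log-ratio comparison gave 0 genes higher and 0 lower (178 at an unadjusted p under 0.05), and the Cy5 comparison 0 and 0 (631), and the lists stayed at 3 higher and 4 lower, and 3 and 7, so the block changed no call counted here. Of 25 genes named by the rule in the log-ratio comparison, 14 changed sign and 25 passed under at least 1 alternative, 8 of them under 1 that kept all arrays. Of 130 named in the Cy5 comparison 6 changed sign and 86 passed under at least 1 alternative, 0 of them under 1 that kept all arrays. Over all pairs of a called list and a setting, the call was kept in 112, lost in 31 and turned in direction in 4 in the log-ratio comparison, and kept in 150, lost in 38 and turned in direction in 2 in the Cy5 comparison.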

Other observations

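The tests on wild-type pool 2, on the distance between the knockout arrays, and on tip genes against pool 2 and lineage share were chosen after the results were seen, while those on other probes and other splits had their prediction written before. Chosen after were also the genes named in the next paragraph.

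Some genes known from the urothelium, the lining of the renal pelvis and ureter, were looked at without a list test, and none passed in the Cy5 comparison (limma adjusted p = 0.806 for each). The membrane plaque gene Upk3a stood at -1.46, Ly6d at -1.66 and the keratin gene Krt5 at -0.82 in knockout minus wild type, and the knockout mean of all 3 lay below each pool. Krt20 (-1.45), Upk1b (-0.94), Upk3b (-0.49), Upk1a (-0.78) and Upk2 (-0.87) were lower mainly than pool 2, with -0.85, -0.37, -0.29, -0.089 and -0.12 against pool 1. The proline-rich genes Sprr2f, Sprr2b and Sprr2e stood at 2.18, 1.09 and 0.77, above both pools. Without KO_vs_WT replicate 2 Krt5 was -0.13 and Ly6d -0.91. Sex-linked transcripts were found in all 4 samples. Xist, expressed from the inactive X chromosome, read 7.41 and 7.94 on the knockout arrays and 6.58 and 7.06 in pools 1 and 2, and the Y-linked Ddx3y read 7.48, 7.44, 7.70 and 7.22 on the log2 scale in the same order, with both well above background in Cy5 on all 4 arrays.

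Wild-type pool 2 held high proximal tubule transcripts. An effect of 1 array or 1 dye is argued against, since the median excess over pool 1 was 2.41 at the least and 2.43 at the most in the 3 channels that carried pool 2, on 2 arrays and in both dyes. Of 20 measured proximal tubule, loop of Henle and distal tubule genes 100% were higher in pool 2, while ureteric bud and collecting duct epithelial genes had a median of -0.23, which is consistent with cells or RNA of other nephron segments in that pool. A sort on fluorescence is meant to remove such cells. Whether they carried the reporter, their RNA was free in the suspension, or they entered in another way was not tested. A biological difference between the animals of the pools stays open and was not tested.

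The probes that stood at least 2-fold higher in knockout also differed between the knockout arrays. Among 51 such probes, replicate 2 lay above replicate 1 by a median of 0.58, or 3.84 times the SD of that difference over all tested probes. Other probes of the same gene, where 1 was tested outside this set, showed a median of 4.14% of the difference. This covered 9 genes, 7 of them under 25%. Other probes of 16 lower genes, taken in the same way, showed 63.5%. Probes that were themselves in the set did not count as other probes, and genes with only such probes dropped out. A low share is thus partly built in and cannot decide on a change of the whole transcript. The 51 probes were chosen by their values on these arrays, which can widen the gap between the knockout arrays. A difference between arrays or labelling reactions thus cannot be told apart from the choice of probes. A whole-transcript change stays open for these genes, and also for genes with 1 probe, such as Sgk1.

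Ureteric bud tip genes were lower in knockout by a median of -0.27. Proximal tubule cells in pool 2 are argued against as the whole cause, since the median against pool 1 was -0.27 as well, below all 10000 random lists. Stromal, endothelial and proliferation lists also lay at percentile 0 against pool 1. Between the knockout arrays the tip list lay at percentile 0.12, and stromal, endothelial and proximal tubule lists at 0. The rank among random lists is thus not particular to tip genes or to genotype. A smaller share of ureteric bud lineage cells is argued against too, since 19 epithelial genes of that lineage outside the tip list had a median of 0.12. In the other splits of the 4 arrays the tip medians were 0.078 and 0.059 in size, and knockout replicate 2 lay below replicate 1 by a median of -0.11. Only 3 splits exist, and whether the knockout arrays held separate pools is not known. A difference between single pools thus cannot be told apart from genotype. That loss of the receptor lowers tip genes, or that the share of tip cells differed between pools, may each be true and was not tested.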
